A study of Caenorhabditis elegans with 2 samples.

How the data were processed

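Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole young adult hermaphrodites of Caenorhabditis elegans that carry the fem-2(b245) mutation and were grown at 20 degrees Celsius, per the labels. A rabbit polyclonal antibody against CEC-7, the protein encoded by Y37D8A.11 on chromosome III, was used for the precipitation. The series holds 1 ChIP library and 1 library of input DNA, both numbered replicate 2, and a processed file was analysed only for the ChIP library. No other replicate was analysed here, so no value below has an error between replicates.

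Per the labels' protocols, worms were frozen and ground, the extract was fixed with formaldehyde and sonicated, and libraries were amplified by PCR after size selection and sequenced on Illumina instruments. Per the submitters' processing notes, BWA was among the tools and ce10 was the genome build. Per the file headers, the coordinates are on WormBase WS220 and the peaks were called with MACS. The MACS version, its settings, the use of the input as its control, read filters and any pooling are not given in the sources used here. The deposited list gives each peak a start, an end and a score by the authors, with no fold enrichment, summit, read count or separate p-value. The scale of this score is not stated in the deposited file. Its lowest value is 50.02, just above the 50 that a cut at a p-value of 1e-05 would leave if the score were 10 times the negative log10 of a p-value, as MACS can write it. The score was used only to rank peaks within this list. Sequencing depth is unknown, and a caller's score and peak number both rise with depth, so absolute peak numbers depend on it.

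The positions were used as deposited. The gene table at hand is RefSeq's for assembly WBcel235, another build, so no gene was placed at a peak and no overlap with gene starts, exons, introns, RNA classes, repeats or base composition was computed. The planned tests of gene starts, genomic class, gene lists and gene classes at peaks, GC content and repeats were therefore not run, and the planned rule for named genes was applied to peak positions: the 20 peaks with the highest score and the 5 widest peaks. From the gene table only names, biotypes (to pick protein-coding genes), chromosome membership and the last gene end of each nuclear chromosome were taken. That last gene end served as the chromosome's length for densities and for dividing chromosomes into arms and centres, so these lengths are approximate.

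Peaks were counted per chromosome and expressed per Mb, with exact Poisson 95% intervals. The density on X was compared with that on the 5 autosomes by a two-sided exact binomial test, with an exact conditional 95% interval of the ratio. The share of peak midpoints on chromosome arms, taken as the outer 33.3% of the length on each side, was compared with 10000 circular shifts of all peaks of a chromosome, which keep the spacing of clustered peaks. Distances between neighbouring midpoints were compared with 1000 draws of even random placement within chromosomes. Median scores were compared by two-sided permutation tests over peaks with 100000 resamples, and score and width by Spearman's rho with as many permutations. P-values were adjusted by the Benjamini-Hochberg method over 7 tests. Peaks are not replicates and neighbouring peaks are not independent. Intervals cover counting error only, and p-values compare this 1 list with random placement or, for scores, with scores shuffled over peaks. Because peaks clustered, the binomial p-values and the Poisson intervals are too small. The score permutations also treat neighbouring peaks as exchangeable, so their p-values may be too small as well.

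The computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The tests were checked on simulated lists of 2767 independently placed peaks. The real peaks were clustered, so the coverage and pass rates below do not carry over to them. For the arm share, the SD of the null was 3.93 percentage points with circular shifts and 0.899 with even placement. With even placement, 6 of 100 lists gave p under 0.05 for X and 4 of 100 for arms. With X set to 0.1 of the autosomal rate and arms to 1.3 times that of centres, the mean estimate for X was 0.0986, the interval held the true value in 98 of 100 lists, and 100 of 100 lists passed both tests. The spacing test gave p under 0.05 in 1 of 20 evenly placed lists. With scores of 900 peaks raised 1.3-fold, 20 of 20 lists passed the permutation of medians, against 1 of 20 without a shift. No group as small as the 17 peaks on X was simulated, so the sensitivity of the score comparison for X is unknown.

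The tests of X density, arms, spacing and score, 16 gene lists and all alternatives except those named next were chosen before the data were examined. The alternatives chosen then were the 50% of peaks with the highest score, called the higher-scoring peaks, merging of peaks less than 1000 bp apart, other definitions of arms, the arms without X, other placements, another distance between neighbours, covered bases in place of peaks and X density in the centres alone. The comparison of chromosome III with V and its alternatives, the comparison of X with chromosome V alone, the look at the first 200 kb of each chromosome, the omission of single chromosomes or of that end of X, the per-gene denominators, the within-chromosome permutation of scores, the scores on arms without X and the spacing of merged regions were added after seeing the data.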

Results

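The binding of CEC-7, a protein named for its chromodomain, was mapped in whole adult hermaphrodites with a germline. Chromodomains are folds that in many proteins bind methylated histone tails. The fem-2 gene, mutated in this strain, acts in sex determination. The list from the single ChIP library held 2767 peaks on the 6 nuclear chromosomes and 0 on mitochondrial DNA, and no peak overlapped the next. The peaks covered 6959636 bases, 6.94% of these chromosomes. Peak width had a median of 1987 bp, with quartiles of 1422.5 and 3124 bp, and ranged from 771 to 14431 bp. The score, the authors' own value for each peak, had a median of 127 and ranged from 50.02 to 1951.83. Sequencing depth was not given in the sources used here, and no replicate stands behind these values.

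The first comparison asked how peaks were divided among the chromosomes. They lay almost wholly on the autosomes. Chromosome III carried 763 peaks and chromosome I 695, followed by II with 567, IV with 434 and V with 291, whereas X carried 17. On X this was 0.614% of all peaks (exact 95% interval 0.358 to 0.982%), although X makes up 17.7% of the sequence and even placement would have put 489 peaks there. The density was 0.959 peaks per Mb on X (exact Poisson 95% interval 0.559 to 1.54) and 33.3 per Mb on the 5 autosomes together. The ratio of X to autosomes was 0.0288 (exact 95% interval 0.0168 to 0.0462), a 34.7-fold lower density (exact binomial p = 1.32e-201, adjusted p = 9.27e-201). Peaks covered 0.227% of X and 8.38% of the autosomes. X was the lowest of the 6 chromosomes, and with chromosomes as the units an exact permutation could not go below p = 0.167. The ratio was 0.0690 against chromosome V alone, 0.0169 among the 50% of peaks with the highest score and 0.00794 in the central 33.3% of the chromosomes.

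The autosomes also differed among themselves. Chromosome III had the highest density, 55.4 peaks per Mb (exact Poisson 95% interval 51.5 to 59.4), and 15.0% of it lay within peaks. Chromosome I had 46.1 per Mb (42.7 to 49.7), II 37.1 (34.1 to 40.3) and IV 24.8 (22.5 to 27.3). Chromosome V, the longest, had 13.9 (12.4 to 15.6), with 3.18% of it covered. The density on III was 3.98 times that on V (exact 95% interval 3.47 to 4.57, exact binomial p = 3.01e-102), a pair chosen after the values were seen. Relative to gene number, III had 289 peaks per 1000 protein-coding genes, I 242, II 165, IV 132, V 58.3 and X 6.23. Chromosome III is also where both cec-7 and fem-2 lie. Whether a peak lay at either gene was not analysed here.

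**Figure D1:**
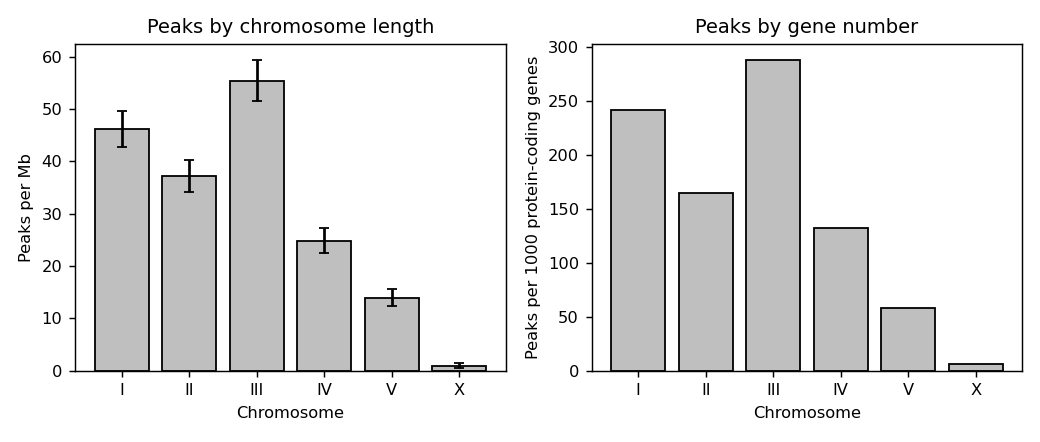
Left, CEC-7 peaks per Mb on each chromosome, with exact Poisson 95% intervals that cover counting error only; right, peaks per 1000 protein-coding genes of the same chromosome. Bars start at 0. Density runs from 55.4 per Mb on chromosome III to 0.959 per Mb on X, and III and X are also the highest and the lowest by gene number.

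Within X the peaks were unevenly spread. The first 200 kb held 10 of the 17 midpoints, at 50.0 per Mb, and the other 7 gave 0.400 per Mb over the rest of the chromosome. An eleventh peak, X 199886 to 200955, began inside that stretch. The group started with a peak at the first base of the chromosome, X 1 to 771 with a score of 58.24. Its strongest member lay at X 42681 to 45371 (score 301.92) and its widest at X 108721 to 114731 (6011 bp, score 128.40). The highest score on X, 313.38, belonged to a peak of 7664 bp at X 7353836 to 7361499, which had a weaker neighbour at X 7352319 to 7353809 (score 69.67). From there, no peak was listed for 8.45 Mb, from X 7361500 to 15806771, up to a single peak of 4848 bp at X 15806772 to 15811619 (score 130.65). The list had no peak midpoint in 13 of the 18 bins of 1 Mb on X, against 0 of 85 such bins on the autosomes. Without the first 200 kb, the ratio of X to autosomes was 0.0120 (exact 95% interval 0.00482 to 0.0247).

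**Figure D2:**
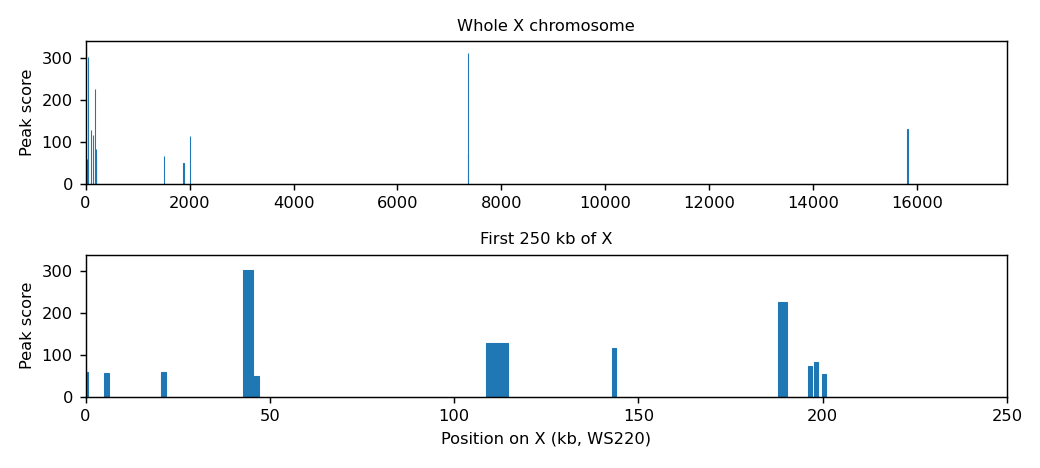
The 17 CEC-7 peaks on X along the whole chromosome (top) and enlarged at its left end (bottom); the horizontal axis is position in kb on WS220, each bar spans a peak, and its height is the peak's score. Of the 17 midpoints 10 lie in the first 200 kb, and none lies between 7361500 and 15806771.

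The second comparison set chromosome arms against centres. In this species the arms hold more repeats and more H3K9 methylation, and the centres more of the conserved, widely expressed genes. Peaks lay more often in the centres than shifted peaks did. Of the 2767 midpoints, 1592 (57.5%) fell in the arms, taken as the outer 33.3% of the length on each side, where circular shifts put 66.6% ± 3.93 (SD of 10000 shifts). The ratio was 0.864 (two-sided circular-shift permutation p = 0.013, adjusted p = 0.0152). All 5 autosomes had a share on the arms below that of their shifts, with ratios of 0.799 on I, 0.925 on II, 0.913 on III, 0.847 on IV and 0.769 on V. None passed on its own, and the lowest single p, 0.042 on V in the circular-shift permutation, became 0.252 after adjustment over 6 chromosomes. The 2 arms of a chromosome were not compared by a test. On chromosome II the left arm held 107 peaks, the centre 217 and the right arm 243, and on I the counts were 231, 326 and 138. The left and right arms held 209 and 255 on III, 133 and 112 on IV, and 77 and 72 on V. On X the left arm held 14, the centre 2 and the right arm 1. The densest 1 Mb bin was on III between 5 and 6 Mb, with 82 peaks.

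**Figure D3:**
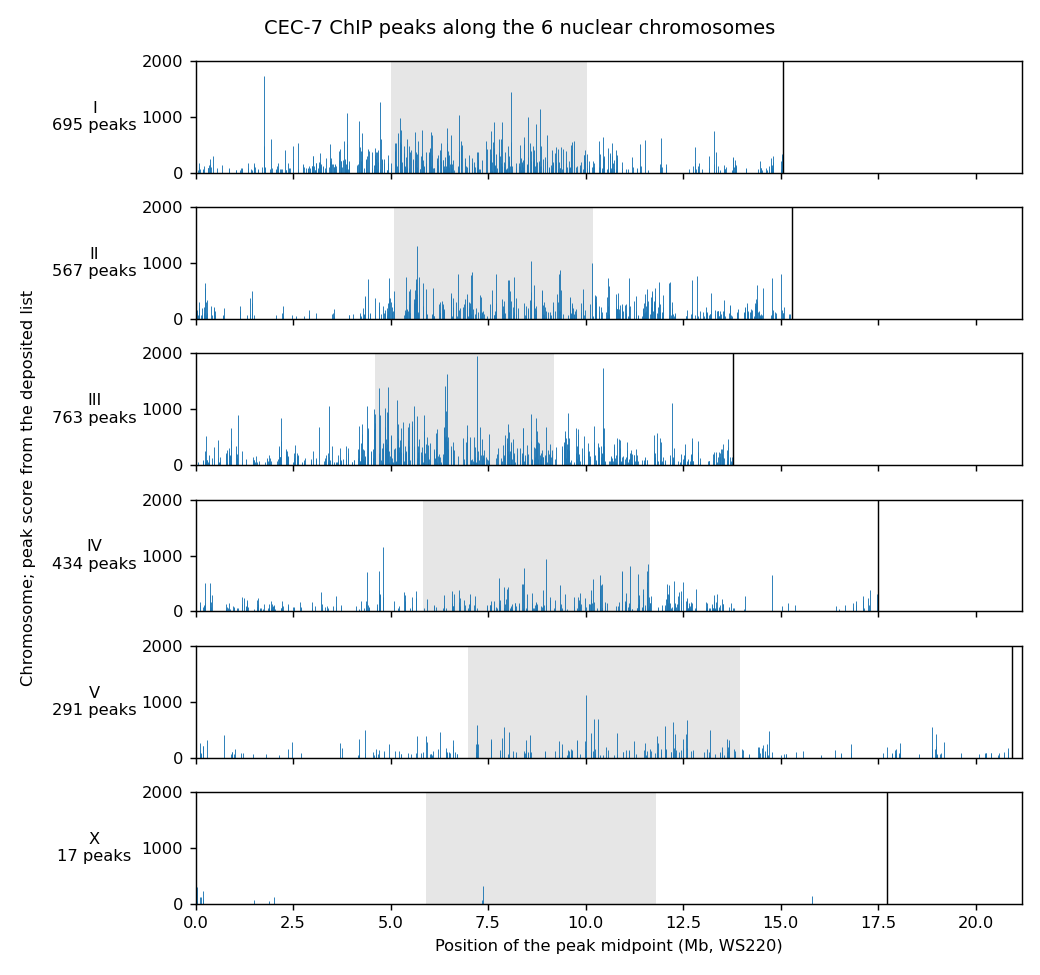
Peak score (vertical axis) against the position of the peak midpoint (Mb, WS220) on each chromosome; each line is 1 peak, grey marks the centre and the black line the chromosome's extent. The 1592 midpoints on the arms are 57.5% of all, and X is nearly empty beyond its left end.

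Peaks in the centres also had higher scores. The median score was 110 on the arms (quartiles 70.8 and 204, n = 1592) and 150 in the centres (quartiles 88.9 and 310, n = 1175). The arms were lower by a difference of medians of -40.1 (two-sided permutation p = 1e-05, the smallest 100000 resamples can give, adjusted p = 1.75e-05). This permutation treats neighbouring peaks as exchangeable, so its p-value may be too small. No shift that keeps neighbours together was run for the score. The median score on X was 72.7 (n = 17) against 127 on the autosomes (n = 2750), a difference of -54.4 that did not pass the permutation test (p = 0.10, adjusted p = 0.10). Score rose with width across peaks (Spearman's rho = 0.789, permutation p = 1e-05, adjusted p = 1.75e-05). Within chromosomes rho ranged from 0.712 on V to 0.820 on II among the autosomes and was 0.478 on X. The same caller gave score and width from the same library, so some relation between them is built in and its p-value says little. Because of this relation, a difference in score is not separate from a difference in width.

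**Figure D4:**
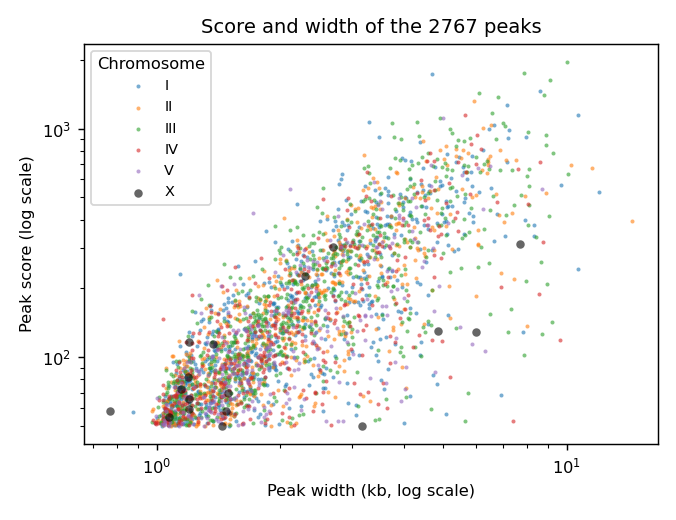
Score against width for each of the 2767 peaks, coloured by chromosome, with log scales on both axes; each point is 1 peak. Score and width rise together (rho = 0.789), and the 17 peaks on X reach a score of 313.38.

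Of the 20 peaks with the highest score, 11 were on chromosome III, 5 on I, 2 on II, 1 on IV, 1 on V and 0 on X, and 12 lay in a centre. All 20 scored 1038.11 or more and were between 3290 and 10614 bp wide. The strongest was III 7223628 to 7233615 (score 1951.83), followed by III 10452630 to 10460490 (1744.51) and I 1755277 to 1759963 (1726.36). The fourth and the sixth were also on III, at 6433034 to 6442100 (1636.81) and 6383388 to 6389485 (1424.42). The fifth, I 8083953 to 8092556, scored 1454.31. The strongest peaks of the other autosomes were II 5669656 to 5675587 (1314.65), IV 4800410 to 4806043 (1147.85) and V 10020525 to 10025508 (1113.84). The widest peaks were not the strongest. The peak at II 11661291 to 11675721 spanned 14431 bp with a score of 392.76. The next, of 11985 bp, reached I 15071786 at the right end of chromosome I, where the ribosomal DNA array lies (score 525.22). No overlap of this peak with the array was computed, and whether the caller used the input as control is unknown. The other 3 of the 5 widest were II 12150743 to 12162257, I 8905669 to 8916285 and I 8828251 to 8838864, and only the last was among the 20 highest scores.

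Peaks were clustered along the chromosomes relative to even placement. Neighbouring midpoints were a median of 7831 bp apart, against 18241 bp with even placement, and 57.0% of peaks had another midpoint within 5 kb, against 32.2% (1000 random placements, two-sided permutation p = 0.001, the smallest they can give, adjusted p = 0.0014). Even placement does not keep broad differences in density along a chromosome, such as those between arms and centres. Local clustering is therefore not separate from these differences in this test. Of 2761 gaps between neighbours on a chromosome, 658 (23.8%) were shorter than 1000 bp. Joining peaks with gaps under 5 kb gave 1391 domains, of which 741 held 1 peak and 94 held 5 or more. The longest such domain spanned 64.9 kb on III, from 5148921 to 5213810, with 13 peaks. The next were III 4887735 to 4947850 with 11 peaks, III 6338245 to 6396272 with 12 and III 6415321 to 6471314 with 10. The longest outside III was II 5639996 to 5693879, with 12 peaks. When peaks less than 1000 bp apart were merged into 2109 regions, the share with a neighbour within 5 kb was 22.6%, below the 25% of even placement, while the median distance stayed shorter, at 15619 bp against 24622 bp. Merging removes the shortest distances, which random placement keeps, so this share does not decide whether merged regions cluster.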

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

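Every alternative with a test that was run for X density, the III to V ratio, the arm share and the score on arms kept its direction and its side of the 0.05 threshold. The X to autosome ratio ran from 0.00794 in the centres to 0.0690 against chromosome V alone, with 0.0169 in the higher-scoring peaks, 0.0311 after merging and 0.0271 by covered bases, a value with no test. The III to V ratio ran from 3.42 after merging to 5.81 in the higher-scoring peaks. The ratio of observed to expected arm share ran from 0.768 in the higher-scoring peaks to 0.885 without chromosome I, and the p nearest the threshold was 0.042, without chromosome V. The difference in median score was -46.4 with arms as the outer 25% on each side and -39.3 without X. The share of peaks with a neighbour within 5 kb reversed against even placement after merging, at 22.6% (random-placement permutation p = 0.041). Merging joins the closest peaks and widens the regions, and how far this accounts for the reversal was not tested. Merged regions lie at least 1000 bp apart and had a median width of 2545 bp, whereas randomly placed midpoints may fall at any distance. The share after merging therefore cannot decide whether regions cluster within 5 kb. Without merging, the share stayed above even placement in the higher-scoring peaks (33.2%) and at 10 kb (78.9%). No alternative was run for the score on X or for score and width, and the list gives no second measure of strength. The alternatives foreseen for gene starts, genomic class, gene lists, gene classes, GC content and repeats were not run, for want of an annotation and sequence of WS220. No paired analysis was possible because each group has 1 library. Unknown depth limits the statements about X: sites weaker than the caller's cut are not in the list.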

Other observations

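The test of a score cut for X and the counts of gene lists by chromosome were chosen after the peak list was seen.

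The fixed gene lists are unevenly spread over the same chromosomes, as counted by chromosome membership alone. X holds 13.7% of the 19971 protein-coding genes. It holds 1 of 64 cytosolic ribosomal protein genes (adjusted p = 0.00417, Fisher's exact test over 16 lists) and 1 of 66 splicing and translation factor genes (adjusted p = 0.00336). It also holds 35 of 1368 chemoreceptor genes (exact test, adjusted p = 2.8e-47) and 20 of 671 genes of the F-box, MATH, pals and C-type lectin families (adjusted p = 8.24e-21). Nuclear hormone receptor genes are fewer on X too, 23 of 269 (exact test, adjusted p = 0.0277). Genes of the neuron list are more frequent there, 37 of 125 (exact test, adjusted p = 1.55e-05). So are those of the intestine list, 22 of 79 (exact test, adjusted p = 0.00323), and of the muscle list, 8 of 27 (adjusted p = 0.0482). The neuron list joins named genes with the flp and nlp families, and the intestine list joins named genes with families such as asp and cpr. Their shares do not stand for neuronal or intestinal genes at large. The other 8 lists did not pass: histones 5 of 81, chromodomain and histone methylation factors 1 of 27, oocyte and germline genes 6 of 66, meiosis genes 1 of 40, sperm genes 19 of 139, collagens 30 of 174, heat shock genes 5 of 54, and dosage compensation and sex determination genes 4 of 22. Chromosome V, the autosome with the fewest peaks per Mb, holds 905 of the 1368 chemoreceptor genes and 167 of the 269 nuclear hormone receptor genes. The exact test counts every gene as placed independently, which members of a gene family grouped on 1 chromosome are not. The p-values of lists made of gene families may therefore be too small. If each gene is given its chromosome's number of peaks per 1000 protein-coding genes, the mean is 211 for the chromodomain list, 196 for splicing and translation factors and 194 for ribosomal proteins. It is 76.9 for the intestine list and 91.3 for chemoreceptors, against 139 over all protein-coding genes. These values were not tested and say nothing of peaks at the genes themselves.

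The first pattern followed up is the scarcity of peaks on X. A smaller number of genes on X is argued against, since the ratio of peaks per 1000 protein-coding genes on X to autosomes was 0.0390 (exact 95% interval 0.0227 to 0.0626). A smaller number of the listed germline genes on X is also argued against as the whole cause. Of the oocyte, germline and meiosis lists, 7 of 106 genes lie there, 6.60% (exact 95% interval 2.70 to 13.1%), against 0.614% of peaks. The oocyte and germline list alone gave 6 of 66 (3.41 to 18.7%). The meiosis list alone gave 1 of 40 (0.0633 to 13.2%), an interval that includes the share of peaks. These lists were chosen by gene name, without expression data. They leave open whether germline-expressed genes at large are scarce enough on X. Weaker X sites that fall below the caller's cut stay open and may contribute: X had 9 of 692 peaks among the 25% with the lowest score, 1.3% (exact 95% interval 0.596 to 2.45%), and 8 of 2075 in the rest, 0.386% (Fisher's exact p = 0.0196). Fisher's test counts neighbouring peaks as independent. Most of these 9 peaks lie at the left end of X, within or just beyond its first 200 kb. The p-value therefore says little about weak sites over the rest of X. The comparison of median scores chosen beforehand, X minus autosomes, gave -54.4 and did not pass (permutation p = 0.10). No biological explanation other than gene number and the named gene lists was tested, since the design has no sample without a germline and no second genotype.

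The second pattern is the group of X peaks in the first 200 kb. An excess at the left end of every chromosome is argued against: on the 5 autosomes together the density in the first 200 kb was 1.08 times that of the rest (exact 95% interval 0.756 to 1.50, 36 peaks). On X it was 125 times (43.0 to 387, 10 peaks). That ratio rests on the near-empty rest of X, at 0.400 peaks per Mb. The window was also chosen after the data were seen, so the X ratio is no independent test against the autosomes. The pooled autosomal value averages unlike chromosomes: the ratio was 4.85 on V (2.55 to 8.42, 13 peaks) and 0.268 on III (0.0552 to 0.786, 3 peaks), while the intervals of I, II and IV included 1. The 50.0 peaks per Mb at this end of X lay within the range of the autosomes' first 200 kb, from 15 per Mb on III and IV to 65 per Mb on V. No biological explanation was tested. Repeats or mapping errors at the end of X stay open because no sequence was used; a peak starts at the first base of X, as 1 also does on chromosome I.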
